A study of Mesocricetus auratus with 18 samples.

How the data were processed

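RNA was measured in frozen liver from 18 male LVG Golden Syrian hamsters, 6 in each of the groups NC, HFD and Wc1982, out of 8 animals per group. Per the labels' protocols, poly(A) RNA was sequenced as 150-bp paired-end reads on an Illumina NovaSeq, animals were housed 2 per cage, and the cage of each animal was not given. All tests and regroupings treat the animals as independent, which could not be checked for animals that shared a cage. HISAT2, StringTie and DESeq2 are named, without version or role, per the submitters' processing notes; the genome build, the annotation and the use of strand are not given in the sources used here. The authors deposited a table of raw counts per gene and library. The authors also deposited a table of FPKM values, scaled by transcript length and library size, for the same libraries. Both tables hold 24464 features, of which 4104 are added features without a gene name that took 1.11 to 1.499% of the counts. Since the counting rules for shared reads, paralogs and overlapping genes are not given, values of near-identical genes are uncertain.

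Gene names were those in the tables. Another 4676 names were locus placeholders, of which 3453 were found in the reference gene table of assembly BCM_Maur_2.0 and 397 took a symbol from it. Of 953 members of 31 gene lists, 814 were matched to a feature. Alternative symbols of the same gene count as separate members here, so an unmatched member need not be a missing gene. For the lists, a protein database symbol in the deposited table was also used where only a single feature without a gene symbol carried it. The list tests took the 30 lists with at least 5 tested members. The list of pancreas, adipose and gut genes, with 3 tested members, is given as values. Total counts per library were 25961020 to 36396379, at which 3 counts equal about 0.1 CPM.

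Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 15407 genes, library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 18 libraries, so that the groups share 1 estimate of the spread. The common biological coefficient of variation was 0.241. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 in a two-sided test. Gene lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, and again with the correlation estimated from the data. List scores were compared by exact permutation over all 924 splits, and intervals for the percent of the diet change reversed came from 10000 bootstrap draws of libraries within groups. Because such intervals are too narrow for 6 libraries, t intervals by the delta method were added after the values had been seen, with CPM and with FPKM and with each library left out. The pool of lists compared with cholesterol synthesis, a mean of scores signed by the diet's direction, was also added then, after intervals for single lists had been read in several ways. CPM is given to 3 or more digits with the SD between libraries, and log2 changes come from the model.

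The lists, the tests, the threshold and the rule for naming genes were fixed before the data were examined. The rule named, for each comparison, the genes past the threshold with the highest and lowest log2 changes and a mean of at least 1 CPM, up to 4 members of each list with the smallest p, 14 genes of lipid and NF-κB biology in all cases, and up to 10 genes that passed in both the diet and the Wc1982 comparison with opposite signs. It gave 211 genes. The texts print some of a subset of 82 of these, and that subset was chosen after the values had been seen, partly because their calls did not rest on a single library; it is therefore somewhat more stable than the full set, in which leaving out 1 library ended 89 of 448 calls, against 28 of 187 in the subset. Stability over settings is given for all 211 genes, of which some are not reported here by name.

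The model was tested on simulated data made from the real means and library sizes for 15172 genes. For HFD against NC it recovered 19.4% of genes changed by 1.5-fold, 61.2% of those changed by 2-fold and 92.4% of those changed by 4-fold, with 7 false calls among 122. For Wc1982 against HFD it recovered 17.9%, 56.7% and 92.4%, with 4 false calls among 115. Only 67, 67 and 66 genes were changed by 1.5-, 2- and 4-fold in the simulation, while 5908 passed for HFD against NC in the real data. Since the adjusted threshold is stricter when fewer genes change, these rates need not hold for the real comparisons. A gene that did not pass may still have changed.

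Alternatives planned from the start were RLE and upper-quartile scaling, DESeq2 1.42.0, voom with sample quality weights, no filter or a filter of 1 CPM in 6 libraries, a fit of only the 12 libraries compared, the replicate number as a block, a threshold of 1 on the log2 change, limma on log2 FPKM with pseudocounts of 1 and 0.1 and with or without a filter at a mean FPKM of 0.5, the list test fry, and leaving out each library in turn. The number of changed members of each list was counted again for each library left out, which was added later. Added after the data were seen were fits without Wc1982 replicates 5 and 6, without these and NC replicate 4 and Wc1982 replicate 3, with 1 surrogate variable from sva 3.50.0, and with offsets for a trend with transcript length, which was taken from the ratio of counts to FPKM. To separate the comparisons that share the HFD libraries, these were split 3 against 3 in 20 ways, and groups without effects were simulated 20 times. For each comparison 100 splits of the 12 libraries, the real one included, were refitted.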

Results

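Liver RNA was sequenced from male LVG Golden Syrian hamsters in 3 groups of 6 libraries, 1 library per animal. NC animals received the normal diet D12102 and oral PBS, HFD animals the high-fat diet D12108C and PBS, and Wc1982 animals the high-fat diet with the bacterium Weissella confusa Wc1982 given daily by gavage. Treatment lasted 6 weeks and livers were taken after a 12-h fast. Total counts per library were 25961020 to 36396379 in NC, 26959221 to 34613143 in HFD and 28333494 to 34163238 in Wc1982. Of 24464 features, 15407 had enough counts to be tested. Expression is given as CPM, counts scaled by library size, as mean ± SD over n = 6 libraries, and every adjusted p of a gene is from edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment. The first principal component of log2 CPM held 34.9% of the variance and placed the Wc1982 libraries, at -3.74 to 23.84, between NC, at -62.9 to -41, and HFD, at 21.35 to 62.76, with an overlap between Wc1982 replicate 6 and HFD replicate 1.

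The comparison of HFD with NC asked what the high-fat diet changed in the liver. Transcripts of cholesterol synthesis, fatty acid oxidation and bile acid handling were lower on the high-fat diet. Transcripts of macrophages, extracellular matrix, cell division and NF-κB signalling were higher. The sterol transporters Abcg5 and Abcg1 rose while most enzymes that make cholesterol fell. In numbers, 5908 genes passed the threshold, 2952 higher and 2956 lower in HFD, and 1496 of the higher and 567 of the lower ones changed by at least 2-fold. With the deposited FPKM values 5923 genes passed, of which 82.7% were higher against 50% with counts, and 3470 were shared. The median log2 change of all genes was 0.178 on the FPKM scale and -0.015 with counts. Small changes are read relative to that shift. The FPKM values were used without the TMM factors applied to counts, which ran from 0.873 to 0.969 in NC and from 0.984 to 1.24 in HFD. Of 30 gene lists 15 passed camera with the preset correlation and 0 with an estimated one, and 19 of 100 splits of the same 12 libraries gave as many lists. The camera calls thus describe direction and the calls of single genes carry the evidence.

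Cholesterol synthesis fell across most of its pathway. Of 19 tested enzymes 15 were lower and 0 higher (16 lower when adjusted over the list alone), with a median log2 change of -1.22 and an adjusted camera p = 3.2e-10 (adjusted p = 0.19 with an estimated correlation). Sqle fell from 13.11 ± 10.13 to 1.719 ± 0.557 CPM (log2 change -2.92 ± 0.42 SE, adjusted p = 2.25e-05) and Fdft1 from 129.5 ± 44.7 to 20.3 ± 6.86 CPM (log2 change -2.67). Ebp fell by 1.95 and the sterol regulator Srebf2 by 0.65 on the log2 scale. The sterol transporters Abcg5 and Abcg1 rose by 3.02 and 3.17 on the log2 scale, and Apoa4 rose by 1.99. Their list of cholesterol efflux and lipoproteins went both ways, with 13 of 36 members higher and 11 lower (also 13 and 11 when adjusted over the list alone), and did not pass (adjusted camera p = 0.12, adjusted p = 0.28 with an estimated correlation).

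Fatty acid oxidation and ketogenesis enzymes were lower for 18 of 30 tested members and higher for 0 (19 lower when adjusted over the list alone; adjusted camera p = 4.9e-07, and adjusted p = 0.21 with an estimated correlation). On the FPKM scale, used without TMM factors, 7 of them were lower and the median change was -0.07. The extent of this fall thus depends on the scaling. Ppara (gene4067) fell from 12.0 ± 7.02 to 4.324 ± 0.885 CPM (log2 change -1.47 ± 0.35 SE, adjusted p = 0.00262) and Cpt1a from 53.97 ± 24.7 to 19.68 ± 4.70 CPM (log2 change -1.45, adjusted p = 0.00361). Acsl1 fell by 0.92 and Ehhadh by 0.93 on the log2 scale. Bile acid genes were lower for 14 of 22 members and higher for 2 (also 14 lower and 2 higher when adjusted over the list alone; adjusted camera p = 2.7e-05, adjusted p = 0.12 with an estimated correlation). Cyp7a1 fell from 17.59 ± 7.15 to 4.423 ± 2.46 CPM (adjusted p = 8.21e-05), and Akr1d1 and Abcb11 by 1.78 and 1.63. Fasn fell by 1.45 on the log2 scale, whereas Srebf1 changed by 0.40 without passing (adjusted p = 0.0508). Other PPAR-α target genes went both ways, 4 of 27 higher and 8 lower (also 4 and 8 over the list alone), and did not pass as a list (adjusted camera p = 0.32, adjusted p = 0.76 with an estimated correlation). Periportal hepatocyte markers fell alongside, lower for 12 of 19 and higher for 2 (13 and 2 over the list alone; adjusted camera p = 0.0032, adjusted p = 0.19 with an estimated correlation; 6 lower and 3 higher on the FPKM scale).

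Inflammatory and matrix transcripts rose together with macrophage markers. Of 25 macrophage and Kupffer cell markers 21 were higher (22 when adjusted over the list alone; median log2 change 1.45, adjusted camera p = 9e-11, adjusted p = 0.18 with an estimated correlation). Extracellular matrix and fibrosis genes were higher for 31 of 39 members (33 when adjusted over the list alone; adjusted camera p = 2.8e-11, adjusted p = 0.19 with an estimated correlation), and proliferation genes for 31 of 36 (32 over the list alone; adjusted camera p = 3.2e-10, adjusted p = 0.19 with an estimated correlation). NF-κB signalling and inflammatory mediators were higher for 23 of 42 and lower for 2 (25 and 2 when adjusted over the list alone; adjusted camera p = 1e-06, adjusted p = 0.18 with an estimated correlation). Gpnmb rose from 0.859 ± 0.366 to 210.2 ± 142.2 CPM (log2 change 7.90), Tlr2 from 0.663 ± 0.329 to 11.11 ± 2.97 CPM (log2 change 4.04) and Timp1 from 0.882 ± 0.343 to 8.11 ± 2.02 CPM (log2 change 3.19). Cd68, Mmp12 and Marco rose by 2.57, 2.95 and 1.94 on the log2 scale. Nfkb2, Nfkbia, Nfkb1 and Rela rose by 1.29, 0.60, 0.57 and 0.32, and Il1b, Tnf and Tlr4 by 1.77, 2.49 and 1.84. Endothelial markers rose by a median of 0.44 (12 of 22 higher, 13 over the list alone; adjusted p = 0.00046, and adjusted p = 0.39 with an estimated correlation), well below the macrophage markers.

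The remaining lists changed less evenly. Interferon-stimulated genes were higher on the high-fat diet for 22 of 41 members and lower for 5 (23 and 5 when adjusted over the list alone; adjusted camera p = 0.00025, adjusted p = 0.19 with an estimated correlation), with Rsad2 higher by 3.35 on the log2 scale. Immediate early genes were higher for 8 of 28 and T and NK cell markers for 11 of 21 (8 and 13 over the lists alone; adjusted camera p = 0.00041 and 0.0053, adjusted p = 0.19 and 0.39 with an estimated correlation). HFD replicate 5 stood apart for T and NK cells, with a score of 2.26 against 1.11 to 1.35 in the other HFD libraries, and without it 6 of these markers were higher. Of the 3 tested pancreas, adipose and gut genes 1 was higher, 0 without HFD replicate 5 and 2 without NC replicate 1, with a median log2 change of 1.15. Genes of glucose metabolism were lower for 17 of 38 and higher for 3 (17 and 4 over the list alone; adjusted camera p = 0.009, adjusted p = 0.18 with an estimated correlation), with 8 lower and 6 higher on the FPKM scale. B and plasma cell markers were higher for 3 of 9 and neutrophil markers for 4 of 7 (4 and 5 over the lists alone; adjusted camera p = 0.031 and 0.038, adjusted p = 0.39 and 0.22 with an estimated correlation); the former was 5 without HFD replicate 2, and the latter 1 without HFD replicate 1 and 2 without NC replicate 1, 3 or 6 or HFD replicate 5. Acute phase, endoplasmic reticulum stress, circadian, xenobiotic and sterol sensing genes did not pass as lists. Nuclear genes of oxidative phosphorylation were lower for 2 of 33 with counts but higher for 14 on the FPKM scale, so no direction is given. Nor is one given for ribosomal protein genes, which were higher for 5 of 56 and lower for 1 with counts, and higher for 37 on the FPKM scale; the 5 were 2 or 3 without NC replicate 2 or 4 or HFD replicate 4 or 5.

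Among the largest single changes, Adra2a rose by 6.44 and Lrtm2 by 4.30 on the log2 scale, while Galnt16 fell by 4.04. Pgc, Fabp4 and Tgm1 also passed. Without HFD replicate 5 the log2 change of Pgc went from 3.35 to 0.23 and that of Fabp4 from 3.32 to 1.12, and neither passed; the rise of Tgm1 was carried by HFD replicates 1 and 2, at 41.98 and 44.45 CPM against 2.26 to 5.37 in the other 4 (NC 0.41 to 2.33), and its log2 change went from 3.40 to 2.81 without replicate 2 alone. The albumin transcript Alb, the most abundant of the named genes, fell from 168100 to 78790 CPM (log2 change -1.09).

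**Figure D1:**
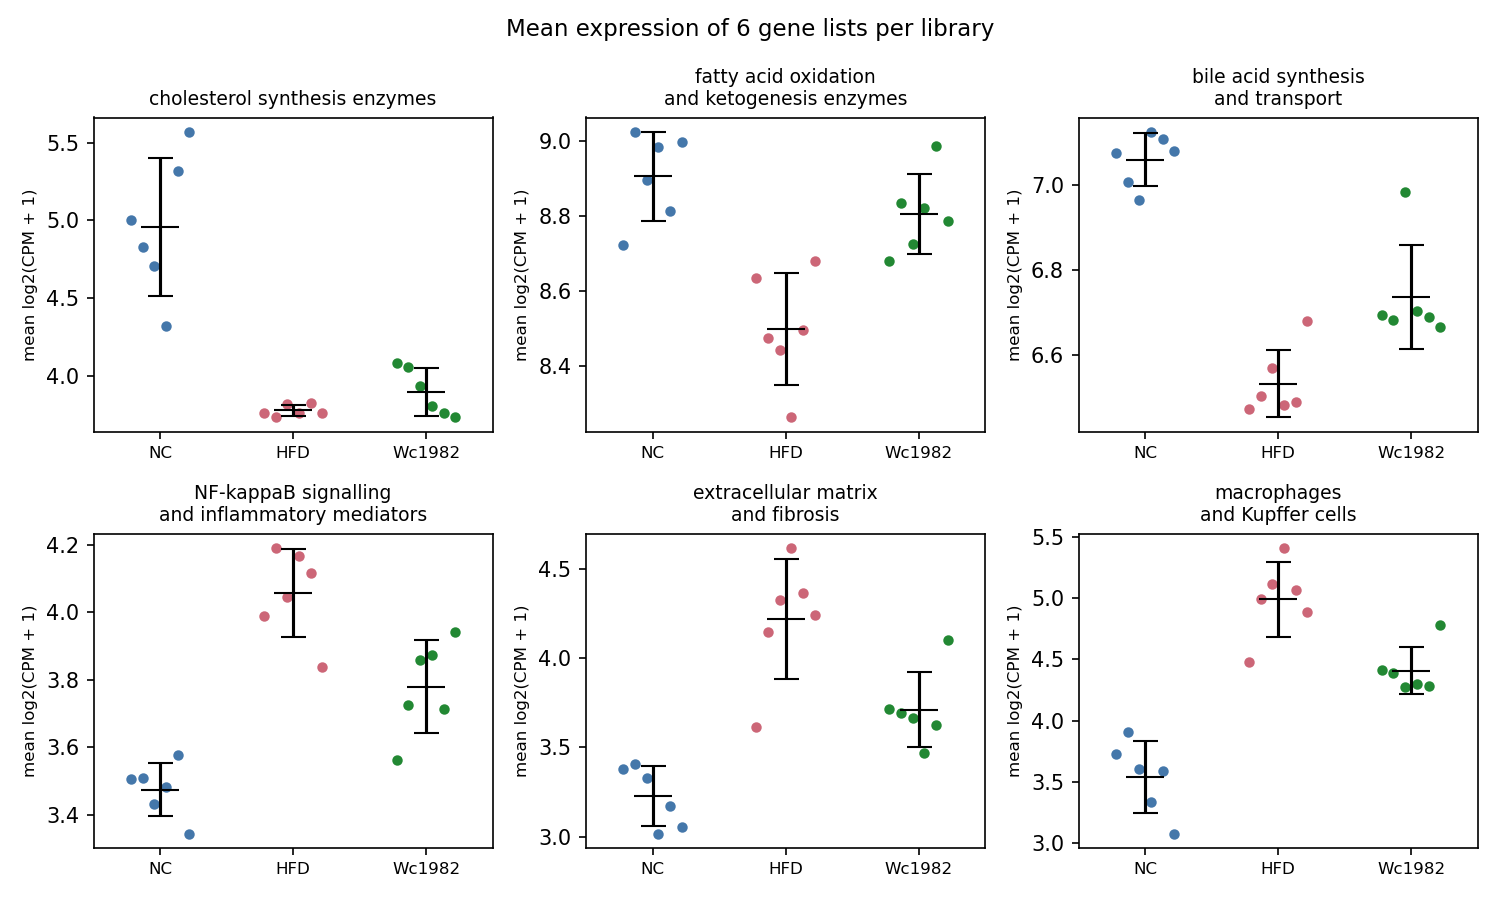
Mean log2(CPM + 1) of the tested members of 6 gene lists, 1 point per library, with the group mean and SD as bars (n = 6 per group). The macrophage list rose by 1.45 on the high-fat diet and fell by 0.59 with Wc1982, while the cholesterol synthesis list fell by 1.18 on the diet and differed by 0.12 with Wc1982 without passing (exact permutation p = 0.1299).

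The comparison of Wc1982 with HFD asked what the bacterium changed on the same diet. Some genes of fatty acid oxidation and bile acid synthesis were higher with Wc1982, and so were Ppara, Cpt1a and Cyp7a1. Most members of these lists, and of the other PPAR-α targets, did not pass. Part of the macrophage, matrix and NF-κB transcripts were lower. Most cholesterol synthesis enzymes did not pass in either direction. In numbers, 1960 genes passed, 1000 higher and 960 lower with Wc1982, and 181 and 237 of them changed by at least 2-fold. This count rested on single libraries, since it was 1221 without HFD replicate 4, 1087 without HFD replicate 5, 1238 without Wc1982 replicate 3 and 1048 without Wc1982 replicate 5. With FPKM values 2018 genes passed, 23.1% of them higher against 51% with counts, with 1297 shared and a median log2 change of all genes of -0.077. Of 30 gene lists 18 passed with the preset correlation and 0 with an estimated one, and 3 of 100 splits gave as many.

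Ppara rose from 4.324 ± 0.885 CPM in HFD to 13.05 ± 7.69 CPM with Wc1982 (log2 change 1.59 ± 0.35 SE, adjusted p = 0.00825). Cpt1a rose from 19.68 ± 4.70 to 68.2 ± 43.7 CPM (log2 change 1.79 ± 0.37 SE, adjusted p = 0.00551). The rise was uneven among the Wc1982 libraries: Ppara was 24.51 and 19.91 CPM in replicates 5 and 6 and 6.13 to 13.36 CPM in the other 4. Without replicates 5 and 6 the log2 change of Ppara was 0.97 (adjusted p = 0.0685) and that of Cpt1a 1.09 (adjusted p = 0.0432), and without these, Wc1982 replicate 3 and NC replicate 4 the values were 0.66 (adjusted p = 0.0662) and 0.86 (adjusted p = 0.0911). Of the 30 oxidation and ketogenesis enzymes 8 were higher and 0 lower (9 higher when adjusted over the list alone; adjusted camera p = 3e-08, adjusted p = 0.19 with an estimated correlation), and 4 were higher on the FPKM scale. The count of 8 was 5 without HFD replicate 3, 4 or 5 and 4 without Wc1982 replicate 5, 3 without Wc1982 replicates 5 and 6, and 1 without these, Wc1982 replicate 3 and NC replicate 4. Acsl1 rose by 0.64 and Ehhadh by 0.63 on the log2 scale, the latter without passing on the FPKM scale. The glycogen regulator Ppp1r3b rose by 1.63, and Dgat2, Elovl5 and Mttp by 0.83, 0.68 and 1.16. Fasn rose by 0.92 without passing (adjusted p = 0.105).

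Bile acid genes were higher for 6 of 22 members and lower for 1 (13 and 1 when adjusted over the list alone; adjusted camera p = 3.9e-05, adjusted p = 0.15 with an estimated correlation). Of these, 3 were higher without HFD replicate 5, 3 without Wc1982 replicates 5 and 6 and 0 without these, Wc1982 replicate 3 and NC replicate 4. The 1 lower member did not pass without HFD replicate 2, 3, 4 or 5 or Wc1982 replicate 1, 2, 4, 5 or 6, and 2 were lower without Wc1982 replicate 3. Cyp7a1 rose from 4.423 ± 2.46 to 9.176 ± 3.23 CPM (log2 change 1.06 ± 0.32 SE, adjusted p = 0.037). It did not pass without HFD replicate 2, 3, 4 or 5 or Wc1982 replicate 1, 2 or 6, when the log2 change ranged over all single omissions from 0.91 to 1.39. Akr1d1 rose by 0.83. Of the 19 cholesterol synthesis enzymes 2 were higher and 0 lower (also 2 and 0 when adjusted over the list alone; adjusted camera p = 0.16, adjusted p = 0.73 with an estimated correlation), and 1 was higher without HFD replicate 4 or 5 or Wc1982 replicate 1, 2 or 3. Fdft1 rose by 0.95 and did not pass without HFD replicate 4 (range 0.80 to 1.05). Sqle changed by -0.69 and did not pass (adjusted p = 0.32). Srebf1 rose by 0.49, a call lost without HFD replicate 1, 2, 4, 5 or 6 or Wc1982 replicate 1, 2, 4, 5 or 6 (range 0.42 to 0.56).

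Parts of the immune, matrix and cell marker lists were lower, and most of these counts rested on single libraries. Macrophage markers were lower for 13 of 25 (16 when adjusted over the list alone; adjusted camera p = 6.1e-08, adjusted p = 0.19 with an estimated correlation) and endothelial markers for 11 of 22 (13 over the list alone; adjusted camera p = 3e-08, adjusted p = 0.19 with an estimated correlation). The macrophage count of 13 was 6 without HFD replicate 4, 7 without Wc1982 replicate 4 and 8 without HFD replicate 5 or Wc1982 replicate 3 or 5. Matrix and fibrosis genes were lower for 20 of 39 and higher for 1 (24 and 1 when adjusted over the list alone; adjusted camera p = 3.7e-09, adjusted p = 0.2 with an estimated correlation). The count of 20 was 9 without HFD replicate 4 and 13 without HFD replicate 3 or 5 or Wc1982 replicate 2, and the 1 higher gene did not pass without HFD replicate 3, 4 or 5 or Wc1982 replicate 5. Proliferation genes were lower for 6 of 36 (9 over the list alone; adjusted camera p = 6.5e-08, adjusted p = 0.2 with an estimated correlation), and for 3 without HFD replicate 4. NF-κB signalling and inflammatory mediators were lower for 12 of 42 and higher for 2 (13 and 2 over the list alone; adjusted camera p = 3.9e-05, adjusted p = 0.19 with an estimated correlation). The lower count was 7 without HFD replicate 4 or 5 or Wc1982 replicate 3 or 5, and the last of these also left 1 higher. Nfkb2 fell from 30.21 ± 6.34 to 19.03 ± 3.00 CPM (log2 change -0.67), Relb by 1.02, Nfkbia by 0.57 and Tlr2 by 1.29 on the log2 scale. Nfkb1 fell by 0.40 and did not pass without HFD replicate 5 or Wc1982 replicate 5 (range -0.46 to -0.33). Rela fell by 0.28 and did not pass without HFD replicate 1, 2, 3 or 4 or Wc1982 replicate 1, 3, 5 or 6 (range -0.32 to -0.22). Il1b fell by 0.86 and did not pass without HFD replicate 4 or 5 or Wc1982 replicate 3 (range -1.01 to -0.69). Tnf and Tlr4 changed by -1.08 and -0.57 and did not pass (adjusted p = 0.0695 and 0.193).

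Timp1, Loxl1, Tgfb1 and Vim fell by 1.43, 1.09, 0.73 and 1.02 on the log2 scale, and the macrophage markers Cd68 and Ctss by 0.87 and 1.00. Gpnmb fell from 210.2 to 70.84 CPM (log2 change -1.57, adjusted p = 0.0276) and did not pass without HFD replicate 4 or 5 or Wc1982 replicate 2, 4 or 5 (range -1.94 to -1.18). Ribosomal protein genes were lower for 17 of 56 and higher for 0 (35 lower when adjusted over the list alone; adjusted camera p = 1.5e-13, adjusted p = 0.21 with an estimated correlation), with a median log2 change of -0.32. On the FPKM scale 40 were lower and the median was -0.44. The count of 17 was 10, 7 and 5 without HFD replicate 3, 4 and 5, and 31, 8, 6, 5 and 6 without Wc1982 replicate 1, 2, 3, 5 and 6. It was 0 without Wc1982 replicates 5 and 6 together. Pgc fell by 3.27, which was -0.14 without HFD replicate 5, and its call also ended without Wc1982 replicate 2, 3 or 5.

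Further lists passed with few changed members. Other PPAR-α target genes were higher with Wc1982 for 5 of 27 and lower for 1 (7 and 1 over the list alone; adjusted camera p = 0.0062, adjusted p = 0.34 with an estimated correlation), 0 were higher without Wc1982 replicates 5 and 6, the 1 lower did not pass without HFD replicate 3, 4, 5 or 6 or Wc1982 replicate 2, 3, 4 or 5, and the score did not differ detectably (difference 0.13, exact permutation p = 0.145, adjusted p = 0.1955). Periportal markers were higher for 5 of 19 and lower for 1 (7 and 1 over the list alone; adjusted camera p = 0.0034, adjusted p = 0.19 with an estimated correlation). That 5 was 0 without Wc1982 replicate 5, 1 without HFD replicate 3 or 5 or Wc1982 replicate 3, 2 without HFD replicate 2 or Wc1982 replicate 2, and 3 without HFD replicate 4 or Wc1982 replicate 1 or 4, and on the FPKM scale 0 were higher. Glucose metabolism genes were higher for 6 of 38 (also 6 over the list alone; adjusted camera p = 0.007, adjusted p = 0.19 with an estimated correlation), 2 without HFD replicate 2 or 5 and 3 without Wc1982 replicate 5. Fatty acid and triglyceride synthesis genes were higher for 3 of 21, and xenobiotic genes higher for 5 of 17 and lower for 1 (3, 6 and 1 over the lists alone; adjusted camera p = 0.0012 and 0.0062, adjusted p = 0.2 and 0.19 with an estimated correlation).

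Interferon-stimulated genes were lower with Wc1982 for 7 of 41 and immediate early genes for 5 of 28 (7 and 6 over the lists alone; adjusted camera p = 0.026 and 0.00018, adjusted p = 0.39 and 0.19 with an estimated correlation). The 7 were 2 without HFD replicate 4, 3 without HFD replicate 5 or Wc1982 replicate 5 and 4 without HFD replicate 2 or Wc1982 replicate 2 or 3, and the 5 were 3 without HFD replicate 5. Markers of T and NK cells, neutrophils and stellate cells were lower for 2 of 21, 1 of 7 and 4 of 20 (1, 1 and 8 over the lists alone; adjusted camera p = 0.0062, 0.014 and 0.00087, adjusted p = 0.4, 0.19 and 0.2 with an estimated correlation). For T and NK cells 1 was lower without HFD replicate 3, 4 or 5 or Wc1982 replicate 1, 2, 3, 4 or 5. For neutrophils 0 were lower without HFD replicate 1, 4 or 5 or Wc1982 replicate 1, 2, 3 or 5, and 2 without HFD replicate 6. For stellate cells 1 was lower without HFD replicate 4, 5 or 6 or Wc1982 replicate 4, and 2 without HFD replicate 3 or Wc1982 replicate 2, 3, 5 or 6.

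**Figure D2:**
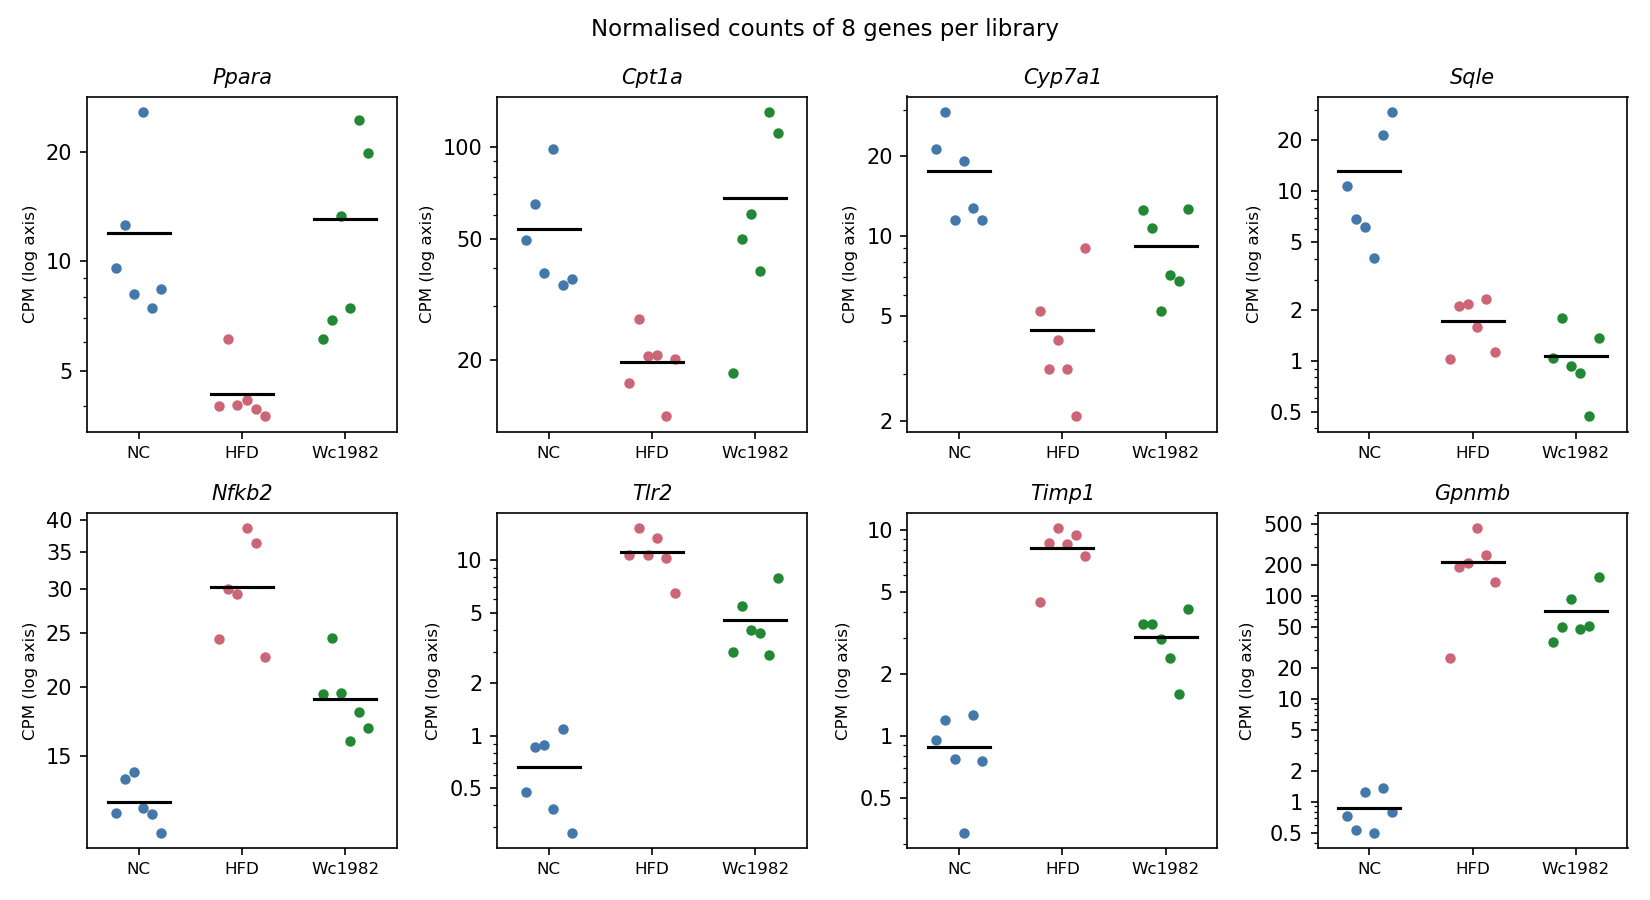
CPM of 8 genes on a log axis, 1 point per library, with a line at the group mean (n = 6 per group). Ppara averaged 12.0 CPM in NC, 4.324 in HFD and 13.05 in Wc1982, where replicates 5 and 6 lie highest.

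The comparison of Wc1982 with NC asked what stayed different from livers on the normal diet. Cholesterol synthesis and part of the bile acid genes were low and the sterol transporters Abcg5 and Abcg1 were high. Most macrophage markers and part of the matrix and NF-κB transcripts were still above NC, by less than in HFD. Fatty acid oxidation was close to NC, with few members past the threshold. In numbers, 2275 genes passed, 1304 higher and 971 lower with Wc1982, and 563 and 164 of them changed by at least 2-fold. With FPKM values 2272 genes passed, 85.8% of them higher against 57.3% with counts, with a median log2 change of all genes of 0.107. Of 30 gene lists 10 passed with the preset correlation and 0 with an estimated one, and 34 of 100 splits gave as many.

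Of 19 cholesterol synthesis enzymes 15 were lower than in NC (16 when adjusted over the list alone; median log2 change -1.06, adjusted camera p = 1.2e-15, adjusted p = 0.18 with an estimated correlation). Sqle was 1.075 ± 0.453 CPM with Wc1982 (log2 change -3.61 ± 0.44 SE, adjusted p = 1.95e-05), Fdft1 lay lower by a log2 change of -1.73 and Ebp by -1.84. Abcg5 and Abcg1 stayed higher by 3.09 and 2.53 on the log2 scale. Macrophage markers were higher for 16 of 25 (also 16 over the list alone; adjusted camera p = 2.3e-09, adjusted p = 0.25 with an estimated correlation), with Gpnmb higher by 6.33 and Tlr2 by 2.75 on the log2 scale. Matrix genes were higher for 14 of 39 (18 over the list alone; adjusted camera p = 1.1e-07, adjusted p = 0.43 with an estimated correlation), which was 7 without Wc1982 replicate 6, 8 without NC replicate 5 and 9 without NC replicate 4 or 6. NF-κB genes were higher for 12 of 42 (also 12 over the list alone; adjusted camera p = 0.00013, adjusted p = 0.31 with an estimated correlation), and for 7 without Wc1982 replicate 6. Ppara and Cpt1a differed from NC by log2 changes of 0.13 and 0.34 and did not pass (adjusted p = 0.854 and 0.588). Oxidation enzymes were lower for 3 of 30 (2 over the list alone; adjusted camera p = 0.046, adjusted p = 0.7 with an estimated correlation), and 2 were lower and 2 higher on the FPKM scale.

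Bile acid genes were still lower than in NC for 9 of 22 and higher for 2 (10 and 2 over the list alone; adjusted camera p = 0.00045, adjusted p = 0.18 with an estimated correlation). Cholesterol efflux and lipoprotein genes were higher for 11 of 36 and lower for 3 (12 and 4 over the list alone; adjusted camera p = 0.012, adjusted p = 0.19 with an estimated correlation), and interferon-stimulated genes higher for 13 of 41 (15 higher and 1 lower over the list alone; adjusted camera p = 0.00013, adjusted p = 0.31 with an estimated correlation). Proliferation genes were higher for 5 of 36 (7 over the list alone; adjusted camera p = 3.7e-06, adjusted p = 0.43 with an estimated correlation), which was 8 and 9 without NC replicate 2 and 3, 3 without NC replicate 4 or Wc1982 replicate 1, 2 or 6, and 2 without NC replicate 5 or 6 or Wc1982 replicate 3. Ribosomal protein genes were lower for 11 of 56 (14 over the list alone; adjusted camera p = 5.8e-07, adjusted p = 0.64 with an estimated correlation), 7 without NC replicate 3 or Wc1982 replicate 2, 5 without Wc1982 replicate 6 and 0 on the FPKM scale.

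The share of the diet's change that was undone with Wc1982 was estimated for the lists whose score changed on the diet (exact permutation, adjusted p below 0.05). For each list the score was its mean log2(CPM + 1), and the percent reversed is given with a bootstrap 95% interval, which is too narrow for groups of 6. It was 75.3% (51.0 to 106.0) for fatty acid oxidation, 51.0% (24.4 to 68.8) for matrix and fibrosis, 47.7% (26.8 to 67.3) for NF-κB and inflammatory mediators, 40.4% (23.8 to 53.9) for macrophage markers and 38.6% (22.2 to 59.4) for bile acid genes. It was 154.2% (71.3 to 355.8) for xenobiotic, 78.3% (52.2 to 112.1) for glucose metabolism, 68.8% (38.2 to 109.3) for immediate early, 49.4% (28.3 to 75.9) for proliferation, 40.1% (-8.9 to 84.4) for antioxidant, 38.4% (18.7 to 58.4) for sterol sensing and 34.9% (15.6 to 56.6) for interferon-stimulated genes, and ranged over the cell lists from -6.8% (-189.2 to 59.2) for erythroid cells to 106.1% (73.2 to 188.5) for endothelium. It was 10.0% (0.6 to 21.1) for cholesterol synthesis and 10.9% (-1.9 to 23.0) for cholesterol efflux and lipoproteins. Where members went both ways on the diet, the mean score sets rises against falls. This holds for efflux (13 higher, 11 lower) and xenobiotic genes (4 higher, 9 lower), whose percentages do not tell how far members moved back. Wider 95% t intervals were 38.2 to 112.5 for fatty acid oxidation and -4.4 to 24.5 for cholesterol synthesis. On the FPKM scale the diet's change in fatty acid oxidation was only -0.14 against -0.41 with CPM, so its percent reversed, 147.7 (-18.2 to 313.6), is not determined there. The score of the cholesterol synthesis list did not differ detectably between Wc1982 and HFD (difference 0.12, exact two-sided permutation p = 0.1299, adjusted p = 0.183 over the lists), while that of fatty acid oxidation did (difference 0.31, exact permutation p = 0.0043, adjusted p = 0.0268). The exact test cannot go below 0.0022 with 6 libraries against 6.

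Across single genes, 1670 passed in both comparisons with opposite signs, 836 higher on the diet and lower with Wc1982 and 834 the other way, and 2 passed with the same sign. Eif4a2, Sema4g and Tspan12 fell on the diet by 1.45, 1.42 and 1.22 and rose with Wc1982 by 0.71, 1.05 and 1.19 on the log2 scale, and Tagln2 rose by 1.63 and fell by 0.92. The count of 1670 was 1059 without HFD replicate 4, 965 without HFD replicate 5, 1093 without Wc1982 replicate 3 and 957 without Wc1982 replicate 5. Independent lists of these sizes would share 183.9 and 191.9 genes in the opposite directions. Because both comparisons use the HFD libraries, opposite signs arise without any effect: across genes, which are not independent replicates, the log2 changes correlated at r = -0.712 against -0.49 in the simulation, with a covariance of -0.293 against -0.0378, a difference of -0.255. With different HFD libraries in each comparison the covariance averaged -0.29 (20 splits, -0.33 to -0.239) and the correlation -0.484, and 509 genes on average (0 to 1205) passed in both with opposite signs. The count filter was looser in these splits because the HFD groups were smaller. Their covariance is thus not over the same genes as -0.293, and the 2 values cannot be compared closely. Of the genes changed by the diet, 1965 still passed against NC with the diet's sign and 3941 did not pass.

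**Figure D3:**
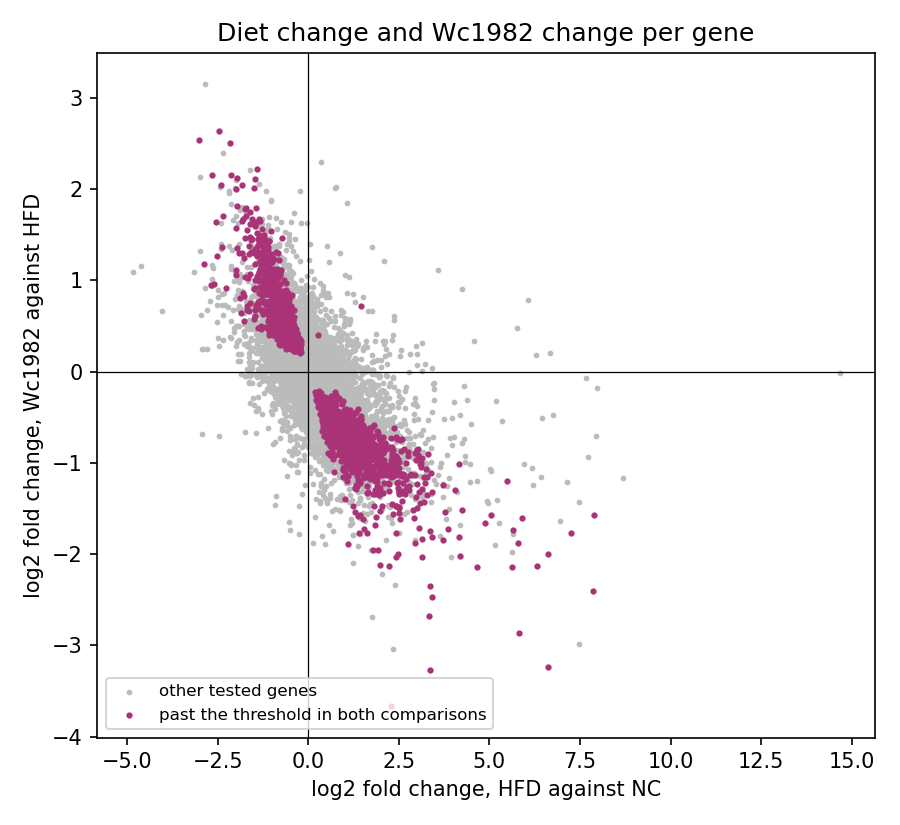
Log2 fold change of each of the 15407 tested genes for HFD against NC (horizontal axis) and for Wc1982 against HFD (vertical axis), with genes past the threshold in both in colour. Of those, 1670 lie in the quadrants of opposite sign and 2 in those of the same sign, and part of the slope comes from the shared HFD libraries.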

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

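The search for single far libraries used a fixed rule, and regrouping the libraries and splitting the HFD libraries were planned. The bound on the covariance over those splits and the tests of hepatocyte share, of cholesterol synthesis and of Ppara and Cpt1a were chosen after the results had been seen. A library was listed when its gap to the nearest of the other 5, divided by the range of its group, exceeded Dixon's 95% critical value. That limit picks about 1 in 20 groups by chance; 24 of 342 groups of gene or list values met it, and 49 of 633 among all 211 genes of the naming rule.

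In HFD, replicate 5 lay apart for Pgc (79.8 CPM against 1.17 to 3.17, gap ratio 0.819), Fabp4 (11.1 against 0.298 to 0.796, ratio 0.855) and Mttp (49.5 against 57.9 to 62.7, ratio 0.664). The same library had the highest scores for T and NK cells (2.26 against 1.11 to 1.35, ratio 0.789), B and plasma cells (3.97 against 2.44 to 2.74, ratio 0.805), pancreas, adipose and gut genes (2.48 against 1.22 to 1.52, ratio 0.758) and ribosomal proteins (7.35 against 7.02 to 7.12, ratio 0.698). HFD replicate 2 was highest for Ppara (6.11 against 3.74 to 4.15 CPM, ratio 0.798) and lowest for Nfkbia (45.0 against 51.8 to 56.2, ratio 0.635). No explanation of these values was tested.

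In Wc1982, replicate 6 was highest for Cd68 (52.2 against 29.6 to 35.8 CPM, ratio 0.666), Ctss (71.6 against 36 to 44.2, ratio 0.701), Tnf (2.18 against 0.693 to 1.09, ratio 0.663), Vim (105 against 60.1 to 69.4, ratio 0.744) and the macrophage score (4.78 against 4.27 to 4.41, ratio 0.728). Replicate 3 was highest for Abcb11 (246 against 104 to 133 CPM, ratio 0.715), Relb (7.91 against 4.05 to 4.81, ratio 0.751) and the bile acid score (6.98 against 6.67 to 6.70, ratio 0.886). Replicate 5 was lowest for Birc5 (1.90 against 3.35 to 4.40, ratio 0.651) and Il1b (2.68 against 6.80 to 10.7, ratio 0.650).

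In NC, replicate 4 was highest for Ahr (29.2 against 10.1 to 14.1 CPM, ratio 0.692), Cat (4810 against 3570 to 3860, ratio 0.737) and Sel1l (11.7 against 5.79 to 7.01, ratio 0.736), and lowest for Tagln2 (26 against 33.4 to 38.5, ratio 0.640). Replicate 1 was lowest for Klf2 (5.14 against 7.18 to 8.67, ratio 0.632).

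Regrouping the libraries tested whether the counts of changed genes could arise by chance. For each of 4 counts, only 1 of 100 splits of the 12 libraries, the real one, gave as many genes. They were HFD against NC (5908, highest other 2364) and Wc1982 against HFD (1960, highest other 1030). The others were Wc1982 against NC (2275, highest other 100) and genes moved back (1670, highest other 894). Chance can thus be excluded for these 4 counts only if single animals are independent. Animals shared cages and the cage of each was not given, so the splits cannot exclude chance differences between cages. For the number of gene lists passing camera in Wc1982 against HFD, 3 of 100 splits gave as many (18 lists, highest other 19). Under the same condition, chance can be excluded there only by the limit of fewer than 5 in 100 splits. With an estimated correlation camera passed 0 of these lists (3 of 30 at an unadjusted p under 0.05), and fry passed 15. Chance cannot be excluded for that number in HFD against NC (15 lists, 19 of 100 splits, highest other 19) or Wc1982 against NC (10 lists, 34 of 100 splits, highest other 14). Scores of single lists are a separate question: in exact permutation tests cholesterol synthesis and 21 other lists passed on the diet (adjusted p below 0.05).

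The partial reversal of the diet's change was weighed against the HFD libraries that both comparisons share and against a lower share of hepatocytes. With different HFD libraries in each comparison the covariance closest to 0 over 20 splits was -0.239, which argues against the shared libraries as the whole cause. A loss of hepatocytes alone would raise all other cell markers alike, but on the diet 3 of 21 pairs of cell lists differed after Bonferroni adjustment in exact permutation tests. All 3 set the macrophage list, which rose by 1.71, against endothelial (0.45), stellate or bile duct markers (members with a mean of at least 1 CPM). No pair without the macrophage list differed, so a lower share of hepatocytes may still be part of the diet's change. For Wc1982 against HFD 0 of 21 pairs differed, with falls from -0.73 for neutrophils to -0.32 for bile duct markers, so a larger share of hepatocytes with Wc1982 stays open and may account for part of the lower immune and matrix transcripts. The exact test is coarse here, as its smallest Bonferroni-adjusted p is 0.0455. Unadjusted, 0 of 21 pairs passed, with the smallest exact permutation p = 0.0519 for macrophage against stellate and against bile duct markers. The lack of a difference thus does not show that the markers fell alike. This test was run in 3 ways: bootstrap intervals on the list scores had set apart 4 of 21 pairs unadjusted and 1 with Bonferroni adjustment, and the exact test was preferred because such intervals are too narrow for 6 libraries and the scores compress scarce transcripts.

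Cholesterol synthesis stayed low with Wc1982, while most other lists that changed on the diet moved back in part. For the mean score of cholesterol efflux 10.9% of the change was reversed with CPM (t interval -6.8 to 28.6) and 20.7% with FPKM (2.0 to 39.3). That score does not tell whether its members moved back, since they went both ways on the diet. Against NC 13 members were higher and 11 lower in HFD, and 11 were higher and 3 lower with Wc1982. By mean log2 changes of the model fits, at most 9.5% of the fall of cholesterol synthesis was reversed over 5 other scalings. With any 1 library left out it was at most 11.9%, and by list scores with CPM at most 12.8%, without Wc1982 replicate 6. The bound of 50 was set after these values were seen. Bootstrap intervals being too narrow for 6 libraries, t intervals were used. The other 21 lists whose score passed on the diet, pooled, were reversed by 45.0 points more (19.6 to 70.4, FPKM 49.0, 18.7 to 79.3). Cholesterol synthesis was singled out after its percent, among the lowest of the lists that passed on the diet, had been seen. The intervals are not adjusted for that choice, so they cannot exclude spread between libraries. The pool also holds cell marker lists, which may follow the share of hepatocytes. With CPM the lower limit was 12.1 without Wc1982 replicate 3 or 4 and also above 0 without replicate 5. With FPKM it was 11.4, 11.8 and 11.6 without these and 12.0, 10.5 and 9.7 without HFD replicate 3, 4 and 5. Taken singly, without adjustment for 6 lists, the difference was 41.0 for matrix (9.7 to 72.3, FPKM 4.6 to 86.8), 37.7 for NF-κB (14.3 to 61.0, FPKM 10.3 to 73.9) and 30.3 for macrophages (7.1 to 53.5, FPKM 3.0 to 70.3). It was 65.3 for fatty acid oxidation (20.1 to 110.5, FPKM -29.2 to 314.4), 28.5 for bile acid genes (-0.0 to 57.1, FPKM -29.1 to 84.5) and 0.9 for cholesterol efflux (-22.0 to 23.8, FPKM -11.0 to 42.2). Single lists thus say less than the pool, which itself does not settle the question of spread. With FPKM and 1 library left out the limits for matrix and macrophages reached 0 in 13 and 14 of 18 omissions, though the differences stayed at 37.4 to 53.7 and 29.1 to 43.6. With CPM the limit reached 0 for matrix in 1 omission, of HFD replicate 4, and for bile acid genes in 15. The high-fat diet that both groups ate stays open as the reason and was not tested.

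The rise of Ppara and Cpt1a with Wc1982 was weighed against an axis between libraries that the groups do not name, seen as a second principal component (9.6% of the variance) with Wc1982 replicates 5, 6 and 3 and NC replicate 4 at one end (-46.65, -45.21, -25.64 and -26.51) and NC replicate 6 and Wc1982 replicate 1 at the other (29.49 and 28.21). A first test left out only the former 4 libraries, which ended both calls in edgeR (Ppara 0.66 ± 0.18 SE, adjusted p = 0.0662; Cpt1a 0.86 ± 0.27 SE, adjusted p = 0.0911), but these include the 3 highest Wc1982 libraries for Ppara, so the fall was fixed by that choice and decides nothing. A surrogate variable, tried after it, gave 0.87 ± 0.26 (adjusted p = 0.0313) and 0.98 ± 0.28 (adjusted p = 0.026) in edgeR, both past the threshold. That variable was estimated from the same libraries with the groups in its model, and the test treats it as known. It therefore cannot decide whether the axis is the whole cause. The folds fell by 0.718 and 0.813, more than their SE of 0.351 and 0.366. The axis may thus be at least part of the rise, and an effect of Wc1982 stays open beside it. It was not weighed for other results. In NC both genes also followed the second component (r = -0.862 and -0.866), less so in HFD (-0.299 and -0.498). The cholesterol synthesis score was lowest in NC replicate 4 (4.32) and highest in NC replicate 6 (5.569), and in Wc1982 lowest in replicates 5 and 6 (3.76 and 3.732). Offsets for transcript length left Ppara at 1.55 and Cpt1a at 1.80, which argues against a length trend.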

How the results depend on the processing

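The fits that leave out 2 or 4 chosen libraries, the surrogate variable, the length offsets and the simulations were chosen after the data were seen; the other settings were planned. The number of genes passing in HFD against NC stayed within 1.5 times of 5908 under every scaling, tool, filter and single omission tried (5319 to 5966 with 1 library left out), except that 2063 passed with a log2 change of at least 1, by construction of that threshold. The same threshold gave 418 genes for Wc1982 against HFD, 727 for Wc1982 against NC and 346 moved back.

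The counts for Wc1982 against HFD and for genes moved back depended most on single libraries. With 1 library left out they ranged from 1048 to 2225 and from 957 to 1936, the low values coming without HFD replicate 4 or 5 or Wc1982 replicate 3 or 5. Wc1982 against NC ranged from 1660 to 2211. Without Wc1982 replicates 5 and 6 there were 978, 1459 and 913 genes for Wc1982 against HFD, Wc1982 against NC and moved back, and without these, Wc1982 replicate 3 and NC replicate 4 there were 269, 1144 and 246; fewer samples lower such counts, and beyond that the cause was not tested.

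The correlation of the log2 changes between both comparisons ranged from -0.735 to -0.681 with 1 library left out. It was -0.614 with no filter on low counts, -0.607 without the 4 libraries and -0.484 with the HFD libraries split. The split also left 3 HFD libraries per comparison and a looser count filter. The causes of these differences were not tested.

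The list calls depended on the correlation assumed. With an estimated correlation 0 lists passed in camera in each comparison (unadjusted p under 0.05 for 6 lists in HFD against NC, 3 in Wc1982 against HFD and 4 in Wc1982 against NC; smallest adjusted p = 0.12, 0.15 and 0.18), against 15, 18 and 10 with the preset one and 21, 15 and 10 with fry, which does not compare a list with other genes. Leaving out 1 library gave 13 to 16, 17 to 19 and 9 to 10.

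No pairing of animals across groups by replicate number was detected, and none is stated: 3 of 18 same-number pairs had a correlation above 0.1, the median was 0.0065, and 8 of 36 best matches were to the same number. With the replicate block 1301 genes passed in Wc1982 against HFD, 5526 and 2034 in the others, and 1148 had moved back with r = -0.694; the cause was not tested.

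Over all 211 genes of the naming rule and 448 calls, single omissions kept 4927 calls and ended 449, planned settings kept 4507 and ended 350, and added settings kept 1531 and ended 261. Reversals occurred 6 times, all on the FPKM scale in HFD against NC, and none passed there; Rpl4 was 0.027 with pseudocount 1, with pseudocount 0.1 and without a filter, against a shift of 0.178 in the median of all genes between these scales. In simulated data, with far fewer changed genes than calls in the real comparison, 1.5-fold changes were mostly missed (19.4% recovered for HFD against NC).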

Other observations

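The relation of Ppara to Cpt1a within groups was looked at only after both had been seen to rise, so it carries no planned test. Across the 6 libraries of each group, log2 CPM of the 2 genes correlated at r = 0.976 in NC (exact permutation p = 0.0028, adjusted p = 0.0084; rho = 0.943, exact p = 0.0167, adjusted p = 0.025), 0.697 in HFD (exact p = 0.1986, adjusted p = 0.1986; rho = 0.829, exact p = 0.0583, adjusted p = 0.0583) and 0.917 in Wc1982 (exact p = 0.0056, adjusted p = 0.0084; rho = 0.943, exact p = 0.0167, adjusted p = 0.025), over 3 relations. Without the 2 libraries farthest from the median of Ppara, r was 0.939, 0.865 and 0.713. This need not be a link between the genes: both followed the second principal component, at r = -0.862 and -0.866 in NC and -0.959 and -0.981 in Wc1982, against -0.299 and -0.498 in HFD. With log2(CPM + 1), 30 of 15392 other genes in NC, 1633 of 15405 in HFD and 1070 of 15405 in Wc1982 followed Ppara at least as closely as Cpt1a did.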
